A study of Mus musculus with 3 samples.

How the data were processed

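RNA was measured in Siglec-F-negative, Ly6C-low, CD64-positive macrophages sorted from mouse colon, from WT (Lyz2-Cre), Tle3cKO and Tle4cKO mice. Per the labels' protocols, cells were pooled by genotype from 4, 3 and 4 mice, sorted at the same time, RNA was taken with TRIzol, and libraries were made by a sequencing company with standard Illumina methods. Read length, strandedness and the number of reads are not given in the sources used here. Groups were taken from the sample titles, with 1 library per group.

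The authors deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for each gene, per the file headers, with 1 table per library and the same 23997 rows in each. Per the submitters' processing notes, TopHat2 version 2.1.0 and Cufflinks version 2.2.1 and the genome build mm10 were used, without the part each tool played. FPKM divides by transcript length and by the depth of the library, so a few very abundant genes can lower all others. The 10 highest genes held 18.9% of the total in WT, 16.6% in the library labelled Tle3cKO and 17.0% in Tle4cKO. Cufflinks divides reads that fit several gene copies by estimation, so rows of near-identical genes are uncertain, as are overlapping and antisense genes. No 2 rows shared a symbol, and 104 rows joined several symbols. Of all rows, 22622 symbols (94.3%) were found in the GENCODE release M21 annotation of the same build, and 99.0% of those overlapped the position in the files. Identifiers and coordinates are from that annotation.

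Because the values are not counts, no count model was used. FPKM steps of low values were compared between libraries to estimate relative depth: over 1846 to 1953 genes under 0.3 FPKM in both libraries, the commonest ratio gave a depth of 0.968 for the library labelled Tle3cKO and 1.21 for Tle4cKO relative to WT. Absolute depth stays unknown, so no counting interval or detection limit is given. An exact 0 can be a failed estimate, and such genes are said to be listed at 0. Of all genes 6988 were at 0 in every library.

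The comparisons were Tle3cKO against WT, Tle4cKO against WT and Tle4cKO against Tle3cKO. Each gene's log2 ratio was computed on FPKM plus a pseudocount of 1, for the 11114 genes with a mean of at least 1 FPKM over the 3 libraries. Genes at a log2 ratio of at least 1 in size were counted. With 1 library per group there was no test. Over all genes the log2 ratios had standard deviations of 0.259, 0.276 and 0.262, which describe genes and not replicates.

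Before the data were examined, 42 gene lists, the genes fixed by name and the alternative settings were written down. The lists covered macrophage states, cytokines and chemokines, signalling and metabolic pathways, antigen presentation, other cell types that a colon sort can hold, sex-linked genes and signs of RNA quality. Tle3 and Tle4 were left out of every list except that of their own family. For the 38 lists with at least 5 measured members, the median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and said to stand apart at a percentile of at most 2.5 or at least 97.5. Mitochondrially encoded genes had no rows, and lists with fewer members got no percentile. In all 3 libraries the Y-linked genes were present and Xist was listed at 0.

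Genes were named by a rule: the targeted genes, the 12 highest and 12 lowest log2 ratios per comparison at a mean of at least 5 FPKM without unnamed, small RNA and receptor segment genes, up to 4 members with the largest differences from each list that stood apart or had at least 3 members past 2-fold, and the fixed genes. Lyz1, the distal X genes outside that rule, further glial genes and 2010005H15Rik and Gm7367 were named after their values were seen. Some genes that the rule takes are not reported here. Since the library labelled Tle3cKO and Tle4cKO were compared with the same WT library, 100 sets of unchanged libraries were simulated from the spread between those 2 libraries, which holds any real difference between these, and their correlation, covariance and overlap are given beside the observed ones.

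With the same spread, the steps were tested on simulated data for the comparison of Tle3cKO with WT, on 11114 genes with 200 of them changed by known folds. Of genes seeded at 4-fold 94% passed the 2-fold threshold in the right direction, of those at 3-fold 82%, at 2-fold 46% and at 1.5-fold 2%. Of 10914 unchanged genes 77 passed it. Of 200 random lists of 25 unchanged genes 4% stood apart, and of the same lists shifted by 0.2 on the log2 scale 99.5% did. Other settings tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, 3 other scalings, leaving out small RNA, ribosomal protein, histone and receptor segment genes, thresholds of 1.5-fold and 3-fold, 10 bins and unmatched random lists, and Spearman's rho. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.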

Results

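RNA-seq was done on macrophages sorted from the colon of untreated male C57BL/6 mice of 3 genotypes. The sorted cells were Siglec-F-negative, Ly6C-low and CD64-positive, a gate that takes resident macrophages and leaves out eosinophils and fresh monocytes. The control mice carried only Lyz2-Cre, which expresses Cre recombinase in myeloid cells, and are called WT. In Tle3cKO and Tle4cKO mice the same Cre was combined with floxed Tle3 or floxed Tle4, genes for Groucho-family corepressors that bind DNA-binding factors and repress their targets. The labels give an age of 9 weeks in one place and 8.9 weeks in another. Cells of 4 WT, 3 Tle3cKO and 4 Tle4cKO mice were pooled by genotype, so each genotype is 1 library. No replicate spread was measured, and no difference given here has a replicate check, a standard error or a p-value.

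The deposited values are FPKM for 23997 genes, with totals of 610714 in WT, 569961 in the library labelled Tle3cKO and 598023 in Tle4cKO. The number of sequenced fragments is not given in the sources used here. From the steps between the lowest values, the library labelled Tle3cKO had 0.968 of the depth of WT, and the Tle4cKO library had 1.21 times that depth. Comparisons used the 11114 genes with a mean of at least 1 FPKM, and every log2 ratio is on the log2(FPKM + 1) scale, which understates differences of low genes. A gene list is described by the median log2 ratio of its members and by the percentile of that median among 10000 random lists matched on expression, where 0 or 100 means outside all of them.

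Tle3 was not lower in the library labelled Tle3cKO. Tle3 (ENSMUSG00000032280.16, chromosome 9, 61372366 to 61418497, mm10) was at 38.6 FPKM in WT, 70.7 in the library labelled Tle3cKO and 46.9 in Tle4cKO. The log2 ratio of the library labelled Tle3cKO to WT was 0.86. Removal of the whole gene would lower it, but loss of some exons need not lower a gene-level value. Tle4 (ENSMUSG00000024642.17, chromosome 19, 14448150 to 14598051) was at 8.5 FPKM in WT, 11 in the library labelled Tle3cKO and 5.8 in Tle4cKO, a log2 ratio of -0.48 for Tle4cKO to WT. Values are summed over each gene, so the deleted exons were not seen separately. The related genes Tle1, at 34.3, 42.3 and 32.4 FPKM in WT, the library labelled Tle3cKO and Tle4cKO, and Tle2, at 1.43, 2.16 and 1.43, were also highest in the library labelled Tle3cKO. Of the 6 measured family members, 5 were higher in that library than in WT, with a median log2 ratio of 0.32.

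**Figure D1:**
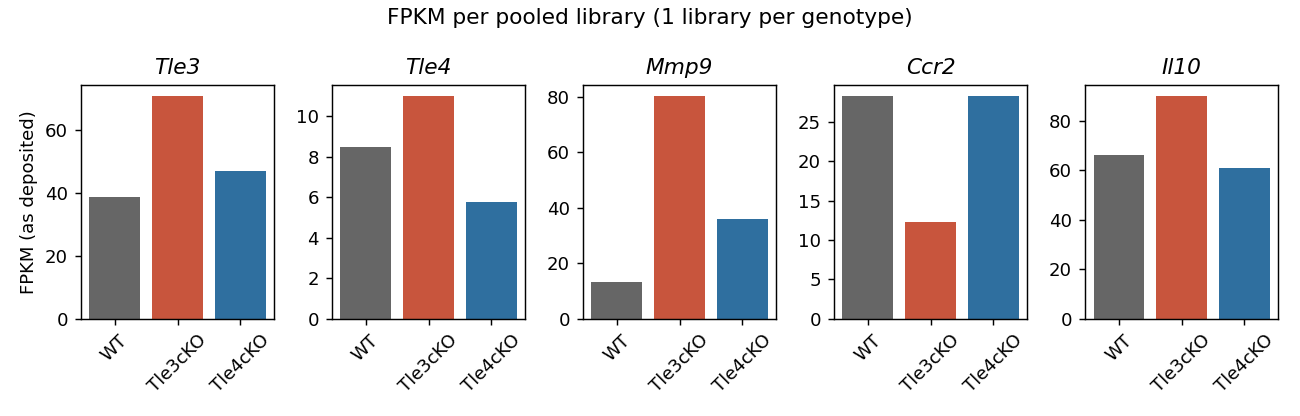
FPKM of 5 genes in WT, the library labelled Tle3cKO and Tle4cKO, drawn as bars from 0 with a separate vertical axis for each gene. Each bar is 1 pooled library, so there are no error bars. Tle3 stands at 38.6, 70.7 and 46.9 FPKM and Mmp9 at 13.3, 80.3 and 36.

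The comparison of the library labelled Tle3cKO with WT asks how the transcriptome of colonic macrophages differs when Tle3 is targeted in myeloid cells. Its directions follow a label that the higher value of Tle3 leaves in doubt. Mmp9, a secreted protease that cuts gelatin and basement-membrane collagen, had the highest log2 ratio of the genes taken by the naming rule. Its FPKM was 13.3 in WT and 80.3 in the library labelled Tle3cKO, a log2 ratio of 2.5 (ENSMUSG00000017737.2, chromosome 2, 164940780 to 164955850). The scavenger receptors Colec12 (2.44 and 16.6 FPKM) and Cd163 (2.92 and 8.98) were higher too, as were Alox5, the 5-lipoxygenase that starts leukotriene synthesis (4.25 and 12.2), and the cystatin Cst7 (3.39 and 9.63). The chemokine receptor Ccr2, which draws monocytes into tissue, was lower, at 28.3 and 12.3 FPKM. So were the chemokines Ccl17 (145 and 47.5) and Ccl8 (26.6 and 10.3), and Il12b, a subunit of IL-12 and IL-23 (4.61 and 1.88). The list of monocyte and early macrophage stage genes, which holds Ccr2, did not stand apart. Its median log2 ratio was -0.04, with 10 members above WT and 13 below (percentile 44.6). In all, 24 genes were at least 2-fold higher and 23 at least 2-fold lower. In the simulated libraries for this comparison 77 of the 10914 genes left unchanged passed 2-fold, but their spread is that of Tle4cKO against the library labelled Tle3cKO, which itself has 81 genes past 2-fold, so this says little of how many of the observed genes would differ without any effect. The observed counts were 90 and 60 with a pseudocount of 0.1, and 7 and 10 with one of 5.

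Interferon-stimulated genes, which are induced by interferon receptor signalling, were lower as a group in the library labelled Tle3cKO. Of 47 measured members 46 were below WT, with a median log2 ratio of -0.39 at percentile 0, though none reached 2-fold. Examples are Irf7, a regulator of the interferon response (37 FPKM in WT and 21.4 in the library labelled Tle3cKO), Ifit3 (27.5 and 16.4) and Gbp4 (19.8 and 10.8). Genes of MHC class II antigen presentation had a median of -0.20 (11 of 13 lower, percentile 0.09), with H2-DMb1 at 303 and 248 FPKM. Cholesterol synthesis genes had a median of -0.16 (22 of 24 lower, percentile 0.03), with Mvk at 2.63 and 1.81 FPKM. Nuclear genes for oxidative phosphorylation subunits had a median of -0.12 (65 of 75 lower, percentile 0). Histone genes had a median of -0.15 at percentile 0, and apoptosis and survival genes one of -0.11 at percentile 0.7. The sizes of these medians depended on the scaling: with equal totals, which moved the median of all genes from -0.01 to 0.08, they were -0.10 for MHC class II, -0.08 for cholesterol synthesis, -0.02 for oxidative phosphorylation, -0.02 for apoptosis and -0.09 for histones, each still below its random lists. With no filter on low genes the histone median was -0.00058, at percentile 11.7.

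Markers of long-lived tissue macrophages, the population that persists in the gut wall without replacement by monocytes, were higher as a group. Of 15 measured members 12 were above WT, with a median log2 ratio of 0.44 at percentile 100. Folr2, a folate receptor, was at 7.34 FPKM in WT and 14.5 in the library labelled Tle3cKO, and the phosphatidylserine receptor Timd4 was at 31.8 and 53. Lyve1 was at 2.03 and 3.1, but it is also in the list of stromal, endothelial and muscle genes, which was higher too (median 0.25). Among the long-lived markers Retnla, an abundant secreted resistin-like protein, went the other way, at 243 and 140.1 FPKM. The median of the long-lived markers lay between 0.21 and 0.64 over the other settings. Complement and efferocytosis genes had a small median of 0.07 at percentile 99.8, with Mertk at 4.46 and 7.65 FPKM and Mfge8 at 21 and 34.7. The unfolded protein response (0.05, percentile 99.98), TGF-beta signalling (0.06, percentile 99.3), Notch pathway (0.10, percentile 98.2) and matrix protease lists (0.03, percentile 99) also lay above their random lists, by small medians. Over the other settings these lay between 0.04 and 0.15, 0.05 and 0.16, 0.06 and 0.17, and 0.02 and 0.13, in the same order. Resident macrophage identity genes lay above their random lists too (percentile 97.9), with a median of only 0.01. It was -0.02 after the trend with transcript length was removed, an alternative chosen after seeing the data. For CC chemokines the median was 0.04 at percentile 98.2 while the mean was -0.20, because Ccl17 and Ccl8 were so much lower than the other members.

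Markers of several other cell types were higher in the same library. B and plasma cell genes had a median log2 ratio of 0.39 (18 of 19 higher, percentile 100), with the B cell receptor component Cd79a at 19.5 and 33.9 FPKM. T, NK and innate lymphoid genes had a median of 0.27 (11 of 13 higher, percentile 99.98). Stromal, endothelial and muscle genes had a median of 0.25 (21 of 26 higher, percentile 100), with the smooth muscle gene Tagln at 12.7 and 23.5 FPKM. Over the other settings these medians lay between 0.23 and 0.53, between 0.15 and 0.38 and between 0.17 and 0.35. Dendritic cell genes had a median of -0.09 at percentile 2.08 but a mean of 0.01, of the other sign. Rmrp and Lars2, whose rows can take up abundant non-coding or ribosomal RNA, were also higher, at 17.9 and 84.3 FPKM and at 165 and 391. The 19 lists outside the middle 95% compare with 1.9 expected of unrelated genes, but members of real lists vary together, so lists land outside more often than that. Of these, the resident identity, CC chemokine, matrix protease, TGF-beta, Notch, complement, unfolded protein response, dendritic cell and histone lists no longer stood apart under at least 1 other setting.

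**Figure D2:**
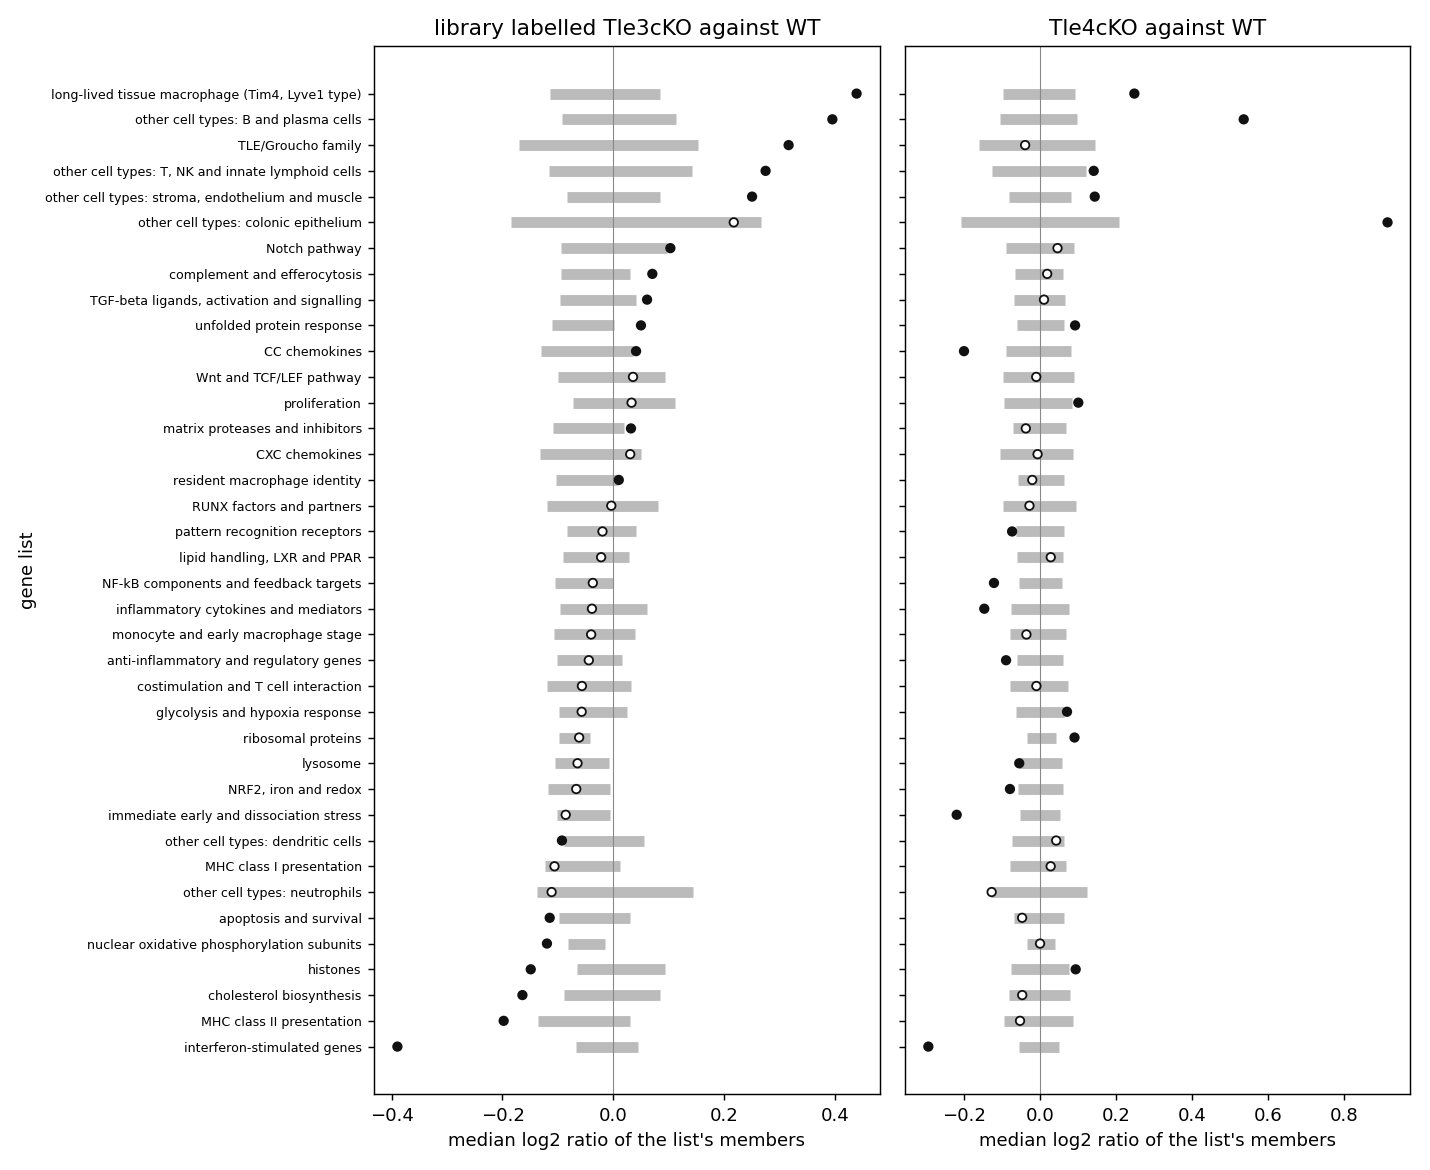
Median log2 ratio of the measured members of each of the 38 gene lists with at least 5 of them, for the library labelled Tle3cKO against WT on the left and Tle4cKO against WT on the right. Grey bars span the middle 95% of 10000 random lists matched on expression, and filled points lie outside them. Interferon-stimulated genes lie lowest in both panels, at -0.39 and -0.29.

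The comparison of Tle4cKO with WT asks the same of Tle4. The value of Tle3 leaves the label of WT in doubt together with that of the library labelled Tle3cKO. Against the latter several directions in Tle4cKO were others: the median log2 ratio was 0.08 for interferon-stimulated genes, -0.21 for long-lived macrophage markers and -0.23 for stromal genes. For CC chemokines it was 0.03, which lay within their random lists (percentile 33.35). Mmp9 was again higher, at 13.3 FPKM in WT and 36 in Tle4cKO. Several lists of inflammatory and stress-response genes were lower by small amounts. The CXC chemokine (-0.006, percentile 46.7), costimulation (-0.009, percentile 41.1) and monocyte-stage lists (-0.04, percentile 17.7) did not stand apart. Immediate early and dissociation-stress genes, which cells switch on within minutes of stimulation or tissue digestion, had a median log2 ratio of -0.22 (28 of 35 lower, percentile 0), with Egr1 at 159.9 and 117 FPKM. In all, 18 genes were at least 2-fold higher and 54 at least 2-fold lower, which were 55 and 104 with a pseudocount of 0.1, and 7 and 15 with one of 5. How many would pass without any effect is not known here either.

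Interferon-stimulated genes had a median of -0.29 in Tle4cKO against WT (45 of 47 lower, percentile 0), with Irf7 at 37 and 21.7 FPKM and Rtp4 at 15.5 and 9.49. CC chemokines had a median of -0.20 (9 of 13 lower, percentile 0.02), with Ccl17 at 145 and 68.2 FPKM and Ccl5 at 283 and 173. Inflammatory cytokines and mediators had a median of -0.15 (16 of 23 lower, percentile 0.01), with Il1b at 815 and 600.3. Their mean was only -0.05, and the members with the largest differences, the low Saa3 (log2 ratio 0.7) and Csf3 (0.5), were higher. NF-kB components and feedback targets had one of -0.12 (24 of 29 lower, percentile 0.01), with the inhibitor Nfkbia at 248 and 210. Anti-inflammatory and regulatory genes were lower as well, with a median of -0.09 at percentile 0.265. NRF2, iron and redox genes (-0.08, percentile 0.86), pattern recognition receptors (-0.07, percentile 1.19) and lysosomal genes (-0.05, percentile 2.3) lay just below their random lists.

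Long-lived tissue macrophage markers had a median of 0.25 (12 of 15 higher, percentile 100), with Timd4 at 31.8 FPKM in WT and 45.9 in Tle4cKO and Folr2 at 7.34 and 10.6, while Retnla was lower, at 243 and 180.4. Ribosomal protein genes differed little but nearly all in one direction, with 75 of 77 higher and a median of 0.09 at percentile 100. The unfolded protein response (0.09, percentile 99.9), proliferation (0.10, percentile 99.1), glycolysis and hypoxia (0.07, percentile 98.6) and histone lists (0.09, percentile 99.3) lay above theirs. In at least 1 other setting the proliferation, pattern recognition, glycolysis, NRF2, lysosome, histone and T, NK and innate lymphoid lists no longer stood apart.

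Of the lists with at least 5 measured members, colonic epithelial genes had the largest median in this comparison, a log2 ratio of 0.91 (6 of 7 higher, percentile 100). Only 7 of the 29 listed genes reached a mean of 1 FPKM, and Muc2, Agr2 and Krt8 did so through Tle4cKO alone, so the difference itself helped to decide which genes were used. The median was 0.37 with no filter on low genes, 1.32 with a pseudocount of 0.1 and 0.39 with one of 5. The goblet cell genes Muc2, the main intestinal mucin (0.128 FPKM in WT and 3.0 in Tle4cKO), and Agr2 (0.468 and 8.1) were among them, and Spink4, also of goblet cells, was listed at 0 in WT and at 18.6 FPKM in Tle4cKO. B and plasma cell genes had a median of 0.54 (19 of 19 higher, percentile 100), with the immunoglobulin J chain Igj at 46.9 and 192 FPKM and Mzb1 at 6.48 and 18.2. The T, NK and innate lymphoid list had a median of 0.14 at percentile 98.8. The stromal list had a median of 0.14 at percentile 99.97 and a mean of 0.03, yet its glial member Gfap went the other way. This intermediate filament gene of glia was at 8.92 FPKM in WT and 3.82 in Tle4cKO. The sodium channel gene Scn7a was at 16 and 5.29, and the prion protein gene Prnp at 75.2 and 33.4.

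Set directly against each other, Tle4cKO and the library labelled Tle3cKO differed by 23 genes at least 2-fold higher and 58 at least 2-fold lower in Tle4cKO, which were 50 and 145 with a pseudocount of 0.1, and 9 and 12 with one of 5. Here too the value of Tle3 leaves the label of the Tle3cKO library in doubt. Ccr2 was at 12.3 FPKM in the library labelled Tle3cKO and 28.3 in Tle4cKO, and Cxcl9, an interferon-gamma-induced chemokine, at 9.48 and 18.3. Colec12 was at 16.6 and 2.61 and Il10, an anti-inflammatory cytokine, at 90 and 61.1. MHC class I genes had a median log2 ratio of 0.18 in Tle4cKO against the library labelled Tle3cKO (17 of 19 higher, percentile 99.98), with the light chain B2m at 2745 and 3236 FPKM. Ribosomal protein genes (0.16, percentile 100), oxidative phosphorylation subunits (0.11, percentile 100), cholesterol synthesis genes (0.09, percentile 99) and interferon-stimulated genes (0.08, percentile 99.6) were higher. Their sizes depended on the settings, with lowest medians of 0.09, 0.05, 0.03 and 0.02 in the same order. Long-lived tissue macrophage markers (-0.21, percentile 0), inflammatory cytokines (-0.15, percentile 0.01), monocyte-stage genes (-0.13, percentile 0) and complement and efferocytosis genes (-0.10, percentile 0.01) were lower. The means were only -0.08 for the cytokines, whose member Il12b was higher (log2 ratio 1.02), and -0.04 for the monocyte-stage genes, whose member Ccr2 was higher (1.14). Epithelial genes, with the same 7 members, were higher by a median of 0.77, which lay between 0.29 and 0.87 over the other settings. This median was the value of Ceacam1, at 5.21 and 9.6 FPKM, and Muc2, Agr2 and Krt8 again passed the filter through Tle4cKO alone. Stromal and glial genes were lower, with a median of -0.23. Histone genes (0.26, percentile 100) were higher, with a median between 0.08 and 0.37 over the other settings. The immediate early (-0.11, percentile 0), NF-kB (-0.04, percentile 0.06), matrix protease (-0.06, percentile 0.27), anti-inflammatory (-0.03, percentile 0.585), CXC chemokine (-0.07, percentile 2.31), neutrophil (-0.19, percentile 0.63) and TLE family lists (-0.38, percentile 0.05) were lower. The TLE family list holds the targeted genes Tle3 (-0.58) and Tle4 (-0.82) among its 6 members, so its percentile rests partly on them. The monocyte-stage, cholesterol synthesis, NF-kB, matrix protease, anti-inflammatory, CXC chemokine and neutrophil lists no longer stood apart under at least 1 other setting.

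The library labelled Tle3cKO and Tle4cKO were compared with the same WT library, which alone makes the 2 sets of log2 ratios move together. Across genes, which are not independent replicates, Pearson's r between them was 0.522, and simulated unchanged libraries sharing a control gave 0.50, with a middle 95% from 0.448 to 0.551. With the library labelled Tle3cKO as the shared one r was 0.440, and with Tle4cKO shared it was 0.536. With WT shared, the covariance was 0.0373 against 0.0339 simulated, a difference of 0.0033, with the observed value inside the simulated range. The simulated libraries took their spread from the difference between the library labelled Tle3cKO and Tle4cKO, so any real difference between these is part of the simulated values. At the 2-fold threshold 3 genes were higher in both, Mmp9 and the unnamed transcripts 2010005H15Rik and Gm7367, where independent lists would share 0.039 and simulated unchanged libraries 11.5, with a middle 95% from 5 to 19.5, so that 3 lies below that range. Genes lower in both numbered 11, where independent lists would share 0.112 and simulated unchanged libraries 11.5, with a middle 95% from 6 to 17.5. These overlaps rest on the label of WT, which the value of Tle3 leaves in doubt. With the library labelled Tle3cKO as the shared one, 8 genes were higher and 9 lower in both others. With Tle4cKO shared, 26 were higher and 12 lower. With 1 control library the controls cannot be split. Neither overlap with WT shared exceeds that of simulated unchanged libraries, so the excess over independent lists may come wholly from the shared WT library.

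Among the genes lower than in WT in both other libraries, Tmsb4x, Tlr7 and Tlr8 are neighbours at the distal end of chromosome X. They lie in a segment whose 9 expressed genes had a median ratio of WT to the library labelled Tle3cKO of 2.01. Tmsb4x, which binds actin monomers, was at 17707 FPKM in WT, 7563 in the library labelled Tle3cKO and 8520.0 in Tle4cKO (chromosome X, 167207093 to 167209315). The receptors for single-stranded RNA Tlr7 and Tlr8 were at 61.8, 29 and 24 FPKM and at 36.8, 11.2 and 13 FPKM in the same order. Sirpb1a was at 10.6, 3.98 and 3.47, and Cox7a1, a muscle form of a cytochrome oxidase subunit, at 4.2, 1.45 and 0.365. Cd300lh was at 16 FPKM in WT, listed at 0 in the library labelled Tle3cKO and at 0.0083 in Tle4cKO. Amd2 and the joined row of Eif3j1 and Eif3j2, which overlap other rows by symbol, differed as steeply between libraries. Cufflinks can divide reads among such copies differently in each library, so these rows are uncertain, and whether this holds for Cd300lh was not tested.

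**Figure D3:**
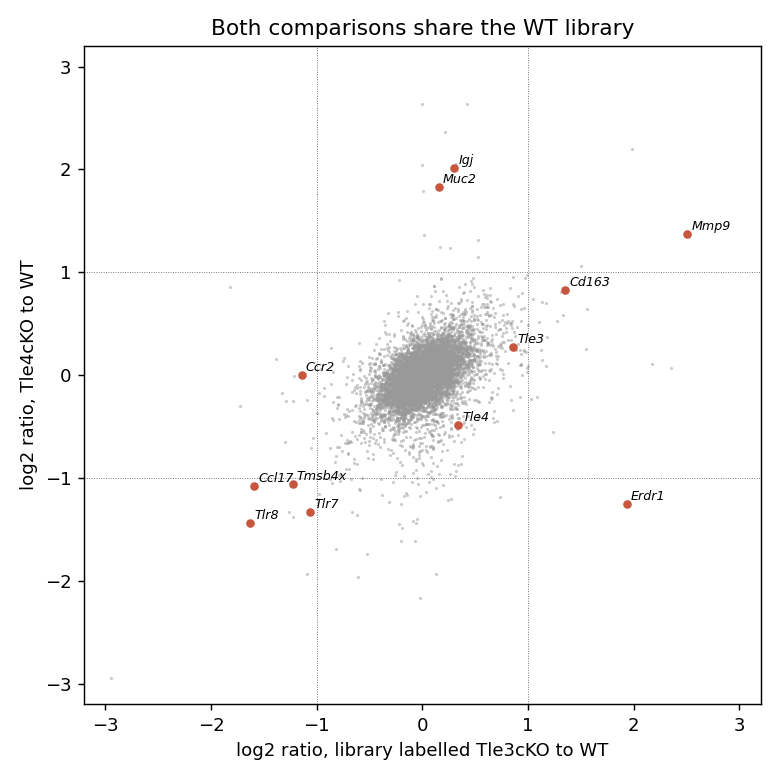
Log2 ratio to WT of the library labelled Tle3cKO (horizontal) and of Tle4cKO (vertical) for 11108 genes as grey points, with named genes in red and dotted lines at 2-fold. Another 6 genes lie beyond the axes. Mmp9 lies at 2.5 and 1.37, and Tlr8 at -1.63 and -1.43.

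**Figure D4:**
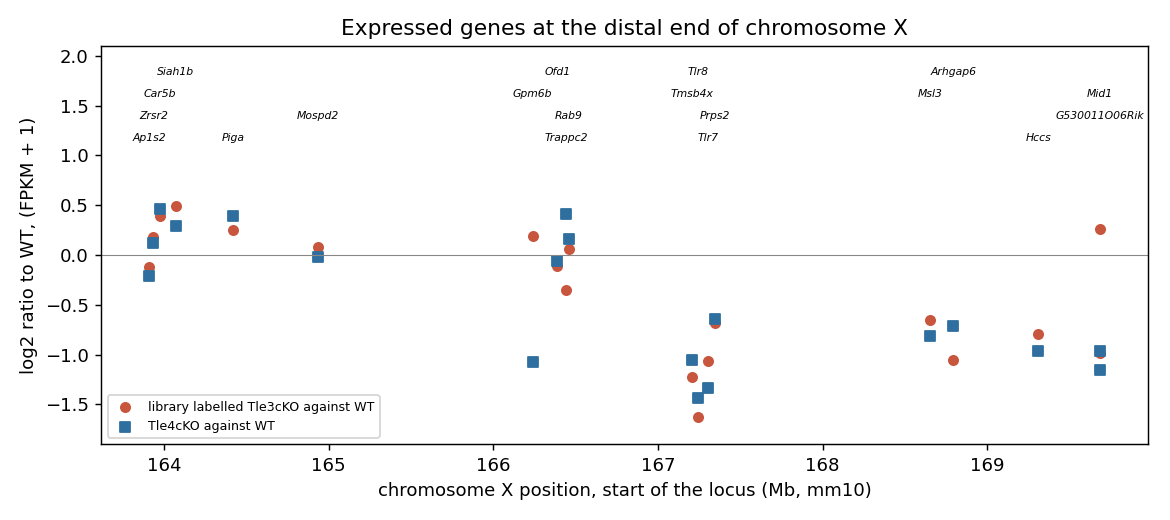
Log2 ratio to WT against position for the last 10 expressed genes before the distal segment of chromosome X and the 9 expressed genes within it, in the library labelled Tle3cKO (circles) and in Tle4cKO (squares). All 9 segment genes lie below 0 except Mid1 in the library labelled Tle3cKO, at 0.26.

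Of the genes fixed by name before the data were examined, Tgfb1 was at 331, 248 and 286 FPKM in WT, the library labelled Tle3cKO and Tle4cKO, Il6 at 22.5, 16.8 and 20.2, Tnf at 68.1, 83.1 and 58.6, Il23a at 0.995, 1.32 and 0.547 and Hes1, a Notch target, at 49.3, 49.1 and 37. Fcgr1, which encodes the CD64 used in the sort, was at 33.3, 36 and 39.2. The Ly6C genes Ly6c1 and Ly6c2 were at 7.57, 11.6 and 9.5 and at 9.38, 5.98 and 6.52, and Siglec5, the symbol under which the files list the Siglec-F gene, was at 2.9, 2.48 and 2.07. Lyz2, whose promoter drives the Cre, was at 10.4, 11.7 and 11.3, with its near-identical copy Lyz1 at 476, 423 and 515, so reads of the pair may have been divided between them.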

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

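With 1 library per group, a difference between the library labelled Tle3cKO and Tle4cKO was noted where a gene passed 2-fold in opposite directions against WT, or where a list stood apart in opposite directions. None of these differences was tested. Erdr1 had a log2 ratio of 1.93 in the library labelled Tle3cKO and -1.25 in Tle4cKO, at 95.2, 367 and 39.5 FPKM in WT, the library labelled Tle3cKO and Tle4cKO. Histone genes had medians of -0.149 and 0.0945, and CC chemokines of 0.0409 and -0.199, in the same order. The mean of the CC chemokines was -0.20 and -0.18, so their difference in sign rests on the median.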

How the results depend on the processing

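The counts of 2-fold genes depended on the handling of low values and on the threshold, and no comparison has a replicate against which to judge them. The counts follow, in the order higher and lower for the library labelled Tle3cKO against WT, then for Tle4cKO against WT, then for Tle4cKO against the library labelled Tle3cKO. They were 24, 23, 18, 54, 23 and 58 as reported. With a pseudocount of 0.1 they were 90, 60, 55, 104, 50 and 145, and with one of 5 they were 7, 10, 7, 15, 9 and 12. A filter at a mean of 5 FPKM, which tests fewer genes (7655), gave 11, 14, 6, 23, 11 and 28. Rescaling to equal totals of 1000000, which also makes the pseudocount of 1 smaller relative to the values, gave 72, 40, 50, 86, 47 and 122. The 1.5-fold threshold gave 177, 121, 134, 189, 99 and 238, and the 3-fold threshold 5, 8, 11, 12, 12 and 8. With no filter, which tests all 23997 genes, 35 were lower for the library labelled Tle3cKO against WT, 32 higher for Tle4cKO against WT and 40 higher for Tle4cKO against the library labelled Tle3cKO. The share of higher genes among 2-fold genes went from 51.1% to 64.3% in the first comparison and from 25% to 36.8% in the second under that rescaling. Leaving out the distal X genes, an alternative chosen after seeing the data, gave 24, 19, 18, 50, 23 and 57.

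Pearson's r between both comparisons with WT lay between 0.478 and 0.555 over 9 other settings, Spearman's rho included. The log2 ratio of Tle3 in the library labelled Tle3cKO to WT lay between 0.80 and 0.96, and that of Tle4 in Tle4cKO to WT between -0.54 and -0.32. For genes named by their rank or fixed by name, 67 differences were past 2-fold. Of these, 43 stayed past it in the same direction in each of 8 settings that kept the gene. None reversed, but a pseudocount or a filter cannot turn the sign of a ratio. Genes named only as members of a list, such as Agr2 and Cox7a1, were not among them. For gene lists, 1279 of 1356 values under other settings kept their state, 53 no longer stood apart, 23 newly did, 1 other moved, and none that stood apart turned to the other side. The number of lists standing apart on the higher side for the library labelled Tle3cKO against WT was 12, and 7 with unmatched random lists; the cause was not tested. Of 19 lists standing apart in each comparison, 10, 12 and 12 did so in every setting, and after removing the trend with transcript length, added after seeing the data, 16, 16 and 19 did. Interferon-stimulated genes, long-lived tissue macrophage markers and the stromal, endothelial and muscle list stood apart in every setting in all 3 comparisons. These comparisons share the same 3 libraries, so they are not separate evidence. The directions differed too, with medians of -0.39, -0.29 and 0.08 for interferon-stimulated genes and 0.44, 0.25 and -0.21 for long-lived markers, in the order above. For the stromal list they were 0.25, 0.14 and -0.23. A property of the single WT library could give the differences of these lists from WT in both comparisons. Keeping only the highest row of a shared symbol was not run, as no symbols were shared. Absolute depth is unknown, so how far sampling noise limits low genes was not measured.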

Other observations

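Of the tests below, the one on glial genes whose values had not been looked at was fixed before its result was seen, and all others were chosen afterwards. A distal part of chromosome X was about 2-fold higher in WT than in the library labelled Tle3cKO and in Tle4cKO. It holds 9 expressed genes from Tmsb4x onward. Besides Tmsb4x, Tlr7 and Tlr8, it takes in Prps2, a phosphoribosyl pyrophosphate synthetase (5.39, 2.98 and 3.10 FPKM in WT, the library labelled Tle3cKO and Tle4cKO), Msl3 (15.6, 9.59 and 8.43), Hccs, a mitochondrial heme lyase (42.0, 23.8 and 21.0), and Arhgap6 (10.3, 4.41 and 5.89). The median ratio of WT to the library labelled Tle3cKO was 2.01, and to Tle4cKO 2.0, against 0.906 and 0.901 for the 10 expressed genes just before the segment.

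For this segment, 0 of 10938 other runs of 9 neighbouring genes had medians as low in both comparisons. The segment was drawn after its genes were seen to be low, so that count cannot decide on a chance run of neighbouring genes. Reads shared with near-identical copies are argued against: the 5 segment genes with under 1% of their 50-base stretches shared with other genes had median log2 ratios of -1.07 and -1.06. A candidate explanation is an extra copy of the segment in the WT mice, as in the Yaa translocation that carries Tlr7 to the Y chromosome. It cannot be told apart from a lowering by loss of either Tle gene, or from a chance run. All 9 genes were chosen for the pattern, no further segment gene was measured at 0.1 to 1 FPKM, 8 of the 9 were lower in both other libraries than in WT, and Mid1, partly at the pseudoautosomal boundary, was at 41.1, 49.5 and 20.6 FPKM. Both the extra copy and the lowering take the labels as given. Were those of WT and Tle3cKO exchanged, the segment would be higher in the Tle3cKO mice than in WT and Tle4cKO, and neither would hold.

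Enteric glial genes were lower in Tle4cKO while epithelial and plasma cell genes were higher. Gfap was at 8.92, 9.34 and 3.82 FPKM in WT, the library labelled Tle3cKO and Tle4cKO, and Sox10 at 1.11, 1.17 and 0.253. A lower share of macrophages would bring up every other cell type alike, and is argued against by a median log2 ratio of -1.55 over the 4 glial genes in the fixed lists, taken with a pseudocount of 0.1. For 23 further glial genes, among them Cdh19 (5.31, 6.59 and 1.74 FPKM), the median was -0.93 against WT and -0.95 against the library labelled Tle3cKO, just short of the bound of -1 set beforehand for fewer glial cells or less glial RNA in the sample. The bound was missed while 22 of the 23 genes were lower than in WT, and several of them, such as Ednrb at 19.4, 21.3 and 21.8 FPKM, may be made by other cells too, so this explanation cannot be told apart from a lowering by loss of Tle4 within the sorted cells; the CD64 gate should have removed glia.

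Tle3 was higher in the library labelled Tle3cKO, by a log2 ratio of 0.86 where 95% of 1117 genes at a like level lay between -0.31 and 0.34. Incomplete deletion of Tle3 would leave it at or below WT, so this value argues against it as the whole cause if the labels are right. Against an exchange of the WT and Tle3cKO labels, Tle3 in Tle4cKO, where it should be intact, had a log2 ratio of -0.58 to the library labelled Tle3cKO, outside the -0.31 to 0.31 of like genes, and of 0.27 to WT, inside their -0.30 to 0.32. An exchange stays open because this rests on 1 library, where loss of Tle4 may act on Tle3, and Tle3 was nearer to WT by 0.31, as were 13 of all 1117 like genes by as much, but 3 of the 17 that differed by at least 0.5 between the library labelled Tle3cKO and WT. A transcript that persists after part of the gene is deleted remains possible too, with a gene-level ratio of 1.83 and no values for single exons, so neither can be told apart here.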
